A study of Homo sapiens with 16 samples.

How the data were processed

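Poly(A) RNA of sorted CD8 T cells had been sequenced from lymph nodes of people with HIV (11 libraries of 5 donors) and tonsils of people without HIV (5 libraries of 2 donors). All sorted populations were CD27high. They were CD45ROlow cells, CD45ROhigh CCR7high CXCR5low cells (called CCR7high here) and CD45ROhigh CCR7low CXCR5high cells (called CXCR5high here). The lymph node groups held 3 CD45ROlow, 4 CCR7high and 4 CXCR5high libraries, and the tonsil groups 2, 2 and 1. Libraries with the same replicate number within a tissue came from 1 donor. Tissue and HIV status go together in this design, so each comparison of lymph node with tonsil is also one of HIV status.

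The deposited table gives FPKM (fragments scaled by transcript length and by mapped fragments) for 23382 genes in 16 libraries. Per the submitters' processing notes, the authors used bcl2fastq 2.17, TopHat2 2.0.13 and Cufflinks 2.2.1 with the hg19 genome. The version of the gene annotation is not given in the sources used here. The table holds no read counts, so absolute depth is unknown. Steps between low FPKM values gave a depth relative to lymph node CCR7high replicate 1 for 13 libraries, from 0.55 to 1.89, and did not resolve 3 libraries. Summed FPKM per library ran from 643871 to 1908233. The single most abundant gene, MIR4461 in 15 libraries, took 11.5% to 51.2% of that sum, and segments of antigen receptor genes took 0.185% to 36.9%. No coordinates are printed, because the table has none and the reference at hand (GENCODE v29) is for GRCh38. Gene symbols are those of the table; 22210 of its IDs were in the reference and 16189 of them had the same symbol there. The table had 0 duplicated IDs and 89 duplicated symbols, 0 identical pairs of libraries and 0 columns belonging to no sample.

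Values were analysed as log2(FPKM + 1) for the 15127 genes with an FPKM of at least 1 in at least 3 libraries. The pseudocount of 1 understates fold changes of genes with low FPKM. A linear model over 6 groups and 16 libraries was fitted with limma 3.58.1 in R 4.3.3 (empirical Bayes with a mean-variance trend, 10 residual degrees of freedom), and p-values were adjusted over genes by the Benjamini-Hochberg method. A gene is called where the adjusted p is under 0.05. In all, 3 comparisons were made within lymph node, 3 between tissues at the same sort and 1 within tonsil, and an interaction asked whether the difference between CCR7high and CD45ROlow differed between tissues. Where a group held a single library, its spread was taken from the other groups. Gene lists were tested with camera at the preset correlation of 0.01 and again with the correlation estimated from the data, with p-values adjusted over the 23 lists within a comparison. Lists of epithelial markers (0 measured genes) and erythroid markers (2 measured genes) were too small to test. For each list, the count of members called was also taken with p-values adjusted over the list alone. Tables were prepared with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

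Groups, comparisons, gene lists, alternative settings and the rule for naming genes were set before the data were examined. In each lymph node comparison the rule names the 12 largest positive and the 12 largest negative log2 fold changes among called genes with a mean log2(FPKM + 1) of at least 1 and the same sign in each donor having both populations. In the other comparisons it names 5 in each direction, or the 5 smallest p-values where none passed. It adds the sort genes CD27, CCR7, CXCR5, CD8A, CD8B and PTPRC, and 2 to 4 members of each list by smallest p. Antigen receptor segments, genes missing from some genomes, genes without a symbol and genes that could help to identify a person are not named. Results of some single genes are not reported here. Genes outside the rule are named with a statement that they were chosen after their values were seen. Genes that share sequence or overlap another gene (FAM153A and FAM153C, LINC00152 and MIR4435-1HG, HLA class II genes, LEF1 and LEF1-AS1) are named with the limit that FPKM may be shared between them, since strandedness is not given in the sources used here.

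The donor pairing was checked on residuals after removal of group means. In lymph node, 9 pairs of libraries from 1 donor had correlations across genes of 0.061 to 0.287 (median 0.12), and 31 pairs from different donors had -0.309 to 0.063. A check for mixed-up libraries found 0 conflicts among the 3 donors with enough clear libraries; 5 libraries gave no clear class. Donor was left out of the model used for reported values, and fits with donor as a fixed block (5 residual degrees of freedom) or a random block (correlation 0.394) were alternatives. In the fixed block, lymph node CXCR5high replicate 2 and CCR7high replicate 3, each the only library of its donor, no longer contribute to any difference, so that fit changes both the block and the libraries compared. The others were pseudocounts of 0.1 and 0.5, no filter on low values, an FPKM minimum of 5, quantile normalization, median-ratio scaling, array weights, a fit to the compared groups alone, no variance trend and omission of each library in turn. Added alternatives, chosen after the data were seen, were omission of both lymph node CXCR5high replicate 2 and tonsil CCR7high replicate 2, the mean of the B cell markers as a covariate, and omission of lymph node CXCR5high replicate 2 in comparisons that do not hold its group. A gene counted as reversed only when it passed the threshold in either setting and its sign differed. A list was followed only in comparisons where it passed with all libraries, and counted as reversed when its direction then differed. A count was the same within 1.5 times.

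The fit was tested on simulated data with the group sizes and spread of this table, in which 50 genes were shifted at each of 4 sizes. Of genes shifted by 1, 2, 3 and 4 log2 units, 8%, 56%, 74% and 90% were called between lymph node CXCR5high and CCR7high, with 9 false calls of 123. The shares were 6%, 38%, 68% and 86% between CXCR5high and CD45ROlow, and 2%, 44%, 72% and 84% between CCR7high and CD45ROlow. Differences of about 1 log2 unit in single genes are therefore mostly missed by the fit to all 16 libraries. Each gene was simulated with the same spread in every library. In the data, array weights gave lymph node CXCR5high replicate 2 a weight of 0.03, against at least 0.205 in the others. The simulated shares do not cover fits without that library. The simulated list that was shifted was called and 0 of the others were. Shifted genes were drawn from those with a mean log2(FPKM + 1) of at least 3. Genes were simulated independently of each other, so the list check does not cover correlation between the genes of a list.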

Results

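RNA of sorted CD8 T cells was available as FPKM for 16 libraries: CD45ROlow, CCR7high and CXCR5high populations of lymph nodes from people with HIV (n = 3, 4 and 4) and of tonsils from people without HIV (n = 2, 2 and 1). The comparisons asked how the CXCR5high population, which carries the receptor that guides cells into B cell follicles, differs in its RNA from the CCR7high and CD45ROlow populations, and which differences go with tissue. Levels are mean FPKM ± SD and differences are log2 fold changes of FPKM + 1 with their SE.

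CXCR5 and CCR7 transcripts separated the lymph node populations along the sort. CXCR5, the receptor for the follicular chemokine CXCL13, was at 45.7 ± 10.1 FPKM in 3 CXCR5high libraries and at 29.4 in replicate 2, against 1.61 ± 0.329 in CCR7high (n = 4) and 1.51 ± 0.739 in CD45ROlow (n = 3). CCR7, which guides cells to the T cell zone, was at 197 ± 45.7 in CD45ROlow, 54.5 ± 18.9 in CCR7high and 10.6 ± 2.46 in 3 CXCR5high libraries, but at 114 in CXCR5high replicate 2. CD8A, a chain of the CD8 co-receptor, was at 376 ± 32.8, 652 ± 87.0 and 749 ± 98.7 in the same groups and at 108 in that replicate. In tonsil, CXCR5 was at 43.5 FPKM in the CXCR5high library (n = 1), and among CCR7high libraries at 1.34 in replicate 1 and 39.5 in replicate 2.

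**Figure D1:**
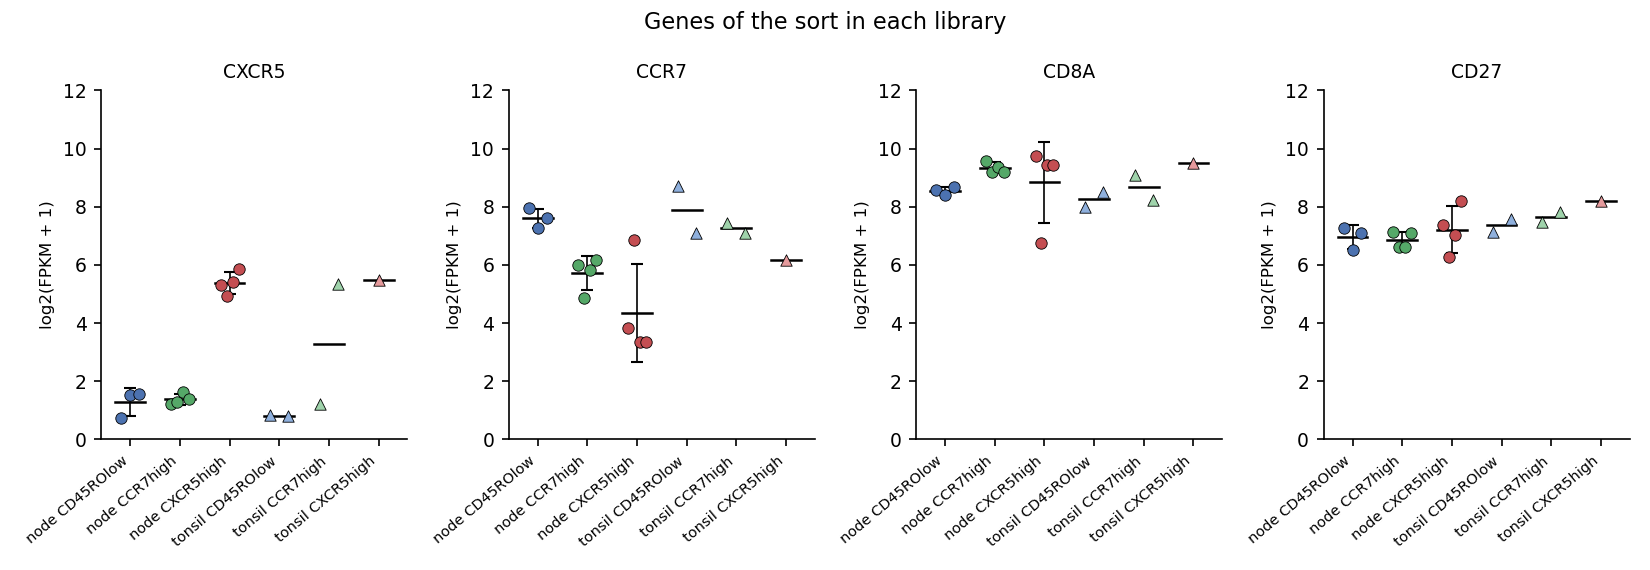
Each point is 1 library; the y axis is log2(FPKM + 1) of CXCR5, CCR7, CD8A and CD27 and the x axis the population (lymph node n = 3, 4 and 4, tonsil n = 2, 2 and 1). Bars are means, with SD where n is over 2; CXCR5 was at 39.5 FPKM in tonsil CCR7high replicate 2 and 1.34 in replicate 1.

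Both libraries whose CXCR5 or CCR7 level departed from their sort also held B cell transcripts. Lymph node CXCR5high replicate 2 had CD79A, a part of the B cell receptor, at 580 FPKM (10.2 ± 7.71 in the other 3) and MS4A1, which encodes CD20, at 305 (9.70 ± 6.25). It listed 68.6% of genes at 0, against 12.9% to 38.3% in the other 15 libraries, and 289 of 2826 broadly expressed genes at 0, against 0 to 1. An FPKM of 0 in that library is therefore given as listed, not as absence. Printed mean levels of its group leave it out, and its own value is given apart. The all-library fold changes, list medians and figure bars include it, so they can differ from the printed levels. Tonsil CCR7high replicate 2 had CD79A at 115.6 FPKM, against 14.49 in replicate 1. These are called the doubtful libraries here. The tonsil CXCR5high library, the only one of its group, held B cell transcripts too, with CD79A at 48.97 and MS4A1 at 28.9 FPKM and a B cell marker mean of 3.847.

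**Figure D2:**
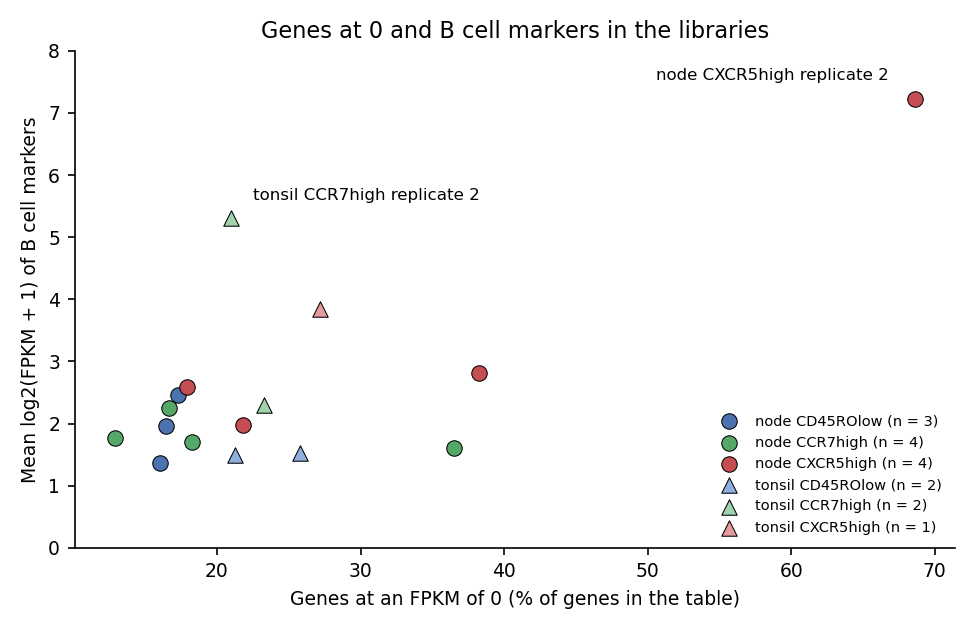
Each point is 1 of the 16 libraries; the x axis is the percent of genes at an FPKM of 0 and the y axis the mean log2(FPKM + 1) of the B cell markers. Lymph node CXCR5high replicate 2 sits at 68.6% and 7.225, and tonsil CCR7high replicate 2 lies highest of the others at 5.301.

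The comparison of lymph node CXCR5high with CCR7high asked what sets the follicular population apart from CCR7high memory cells. LEF1, a transcription factor of naive and memory precursor cells, was at 10.7 ± 4.47 FPKM in CXCR5high (n = 3, 17.9 in replicate 2) and 91.9 ± 39.8 in CCR7high (n = 4). IL7R, the receptor for the survival cytokine IL-7, was at 25.0 ± 6.07 (31.6 in replicate 2) against 129 ± 21.0. SPRY1, a brake on growth factor signalling, was at 0.575 ± 0.216 (listed at 0 in replicate 2) against 7.76 ± 2.67, and NELL2, a secreted protein of naive CD8 T cells, at 16.1 ± 2.08 (56.5 in replicate 2) against 76.3 ± 2.97. With all 16 libraries limma called 0 genes (smallest adjusted p = 0.0653, 1355 genes had an unadjusted p under 0.05). It called 15 (3 higher, 12 lower) without CXCR5high replicate 2, 1 without CCR7high replicate 3, and 20 (1 higher, 19 lower) with donor as a block, a fit in which CXCR5high replicate 2 and CCR7high replicate 3 drop out because their donors have no other library. Of these, 10 genes were shared by the fits giving 15 and 20, all in the same direction. Those fits compare nearly the same libraries, so their agreement is not independent. Over the other settings the count ran from 0 to 52, the highest with array weights. LEF1 differed by -2.75 (SE 0.4, adjusted p = 0.0653, 0.0168 without replicate 2 and 0.00618 with the donor block), SPRY1 by -2.60 (0.0653, 0.0148 and 0.0157) and IL7R by -2.25 (0.0902, 0.0395 and 0.0106), each lower in 3 of 3 donors. CXCR5 differed by 3.9985 (SE 0.651, adjusted p = 0.0902, 0.0395 without replicate 2 and 0.0653 with the donor block) and CCR7 by -1.37 (0.517, 0.0487 and 0.0106). Over all alternatives the adjusted p ran from 8.3e-05 to 0.543 for LEF1, 0.000339 to 0.543 for SPRY1, 0.00185 to 0.354 for IL7R and 0.000902 to 0.731 for CCR7. For CXCR5 it ran from 4.45e-05, without both doubtful libraries, to 0.354, without CCR7high replicate 5.

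Among the genes called without replicate 2, NELL2 had the smallest adjusted p (-2.18, SE 0.192, adjusted p = 0.000417). DKK3, a secreted modulator of Wnt signalling, was higher in CXCR5high (2.36, adjusted p = 0.021), at 32.3 ± 9.57 FPKM (n = 3, 229 in replicate 2) against 5.49 ± 1.71. TXK, a kinase of T cell receptor signalling, was lower (-2.29, adjusted p = 0.0395), at 1.498 ± 0.259 (n = 3, listed at 0 in replicate 2) against 11.7 ± 3.97. TRABD2A (-2.46), CHRM3-AS2 (-2.172), TMEM123 (-1.61), SCML1 (-1.75), RASGRF2 (-2.06) and GDPD5 (-2.24) were also lower, with adjusted p from 0.0234 to 0.0395. With the donor block, S1PR1, the receptor that lets T cells leave lymphoid tissue, was called and fell by 1.68 (adjusted p = 0.0157). S1PR1 was at 7.16 ± 3.46 FPKM in CXCR5high (n = 3) against 20.5 ± 11.4 in CCR7high, but at 158 in CXCR5high replicate 2. TNFRSF25 (-2.46, adjusted p = 0.00607) and CD248 (-2.65, 0.0106) were lower in that fit too. These genes outside the all-library calls were chosen after their values were seen.

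**Figure D3:**
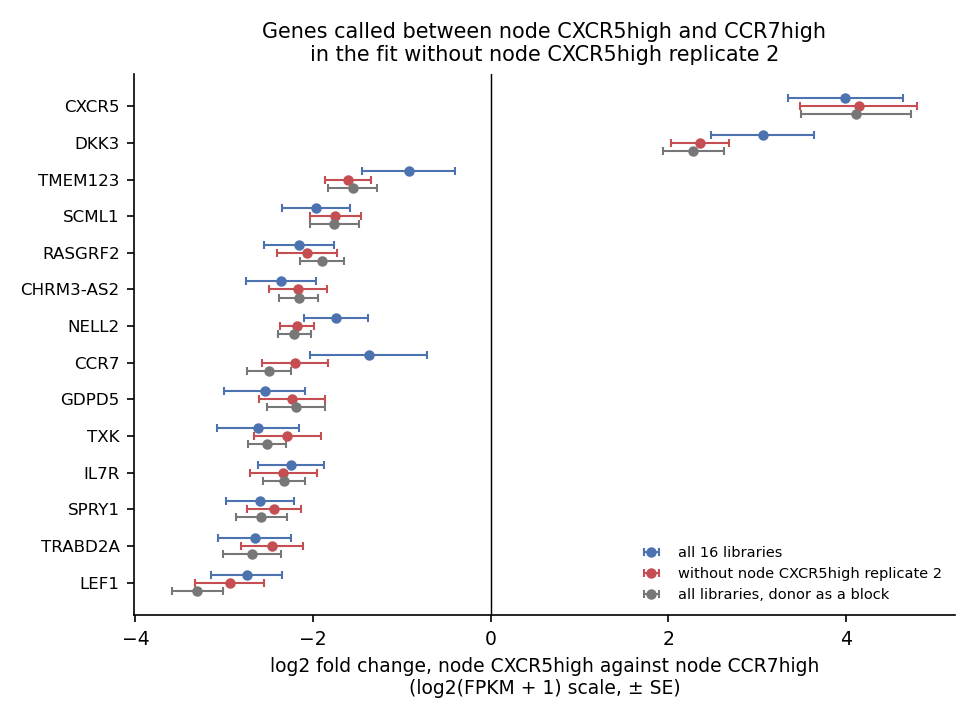
Points are log2 fold changes on the log2(FPKM + 1) scale and bars their SE for 14 genes between lymph node CXCR5high and CCR7high, from 3 fits: all 16 libraries, without CXCR5high replicate 2, and with donor as a block. CXCR5 lies at 3.9985 and LEF1 at -2.75 with all libraries.

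Naive and recirculation genes, which mark cells circulating through the T cell zone, had a median of -1.17 between CXCR5high and CCR7high (0 of 19 called, adjusted over the list alone 0 higher and 9 lower, camera adjusted p = 1.22e-09, lower in 3 of 3 donors). That became adjusted p = 0.171 with an estimated correlation. With the donor block 7 were called lower and 0 higher (adjusted over the list alone 17 lower), the median was -1.50 and the list held with an estimated correlation (adjusted p = 0.00798). Without replicate 2, 5 were called lower (median -1.34, 0.0523 with an estimated correlation). Cytotoxic effector molecules, the proteins of target cell killing, had a median of -0.30 with all libraries (0 of 20 called, camera adjusted p = 0.499), 0.84 without replicate 2 (2.97e-06, adjusted p = 0.677 with an estimated correlation) and 0.91 with the donor block (2.05e-07, 0.728), and were higher in 3 of 3 donors. The differences of the cytotoxic list mean in these donors ran from 0.351 to 1.539, the largest in replicate 5. That CXCR5high library listed 38.3% of genes at 0, the highest share after replicate 2, and its relative depth was not resolved. GZMA, a granule protease, was at 934 ± 766 FPKM in CXCR5high (n = 3, 21.0 in replicate 2) and 244 ± 60.1 in CCR7high, and GZMK at 543 ± 273 (136) against 219 ± 81.1. Neither was called without replicate 2 (adjusted p = 0.604 for both). GZMB was at 149 ± 75.9 (36.2 in replicate 2) against 100 ± 91.9.

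Genes of the follicular helper programme of CD4 T cells were not called between CXCR5high and CCR7high with all libraries. Their median was 0.30 (0 of 22 called, adjusted over the list alone 1 higher and 1 lower, camera adjusted p = 0.105), and 0.05 without replicate 2 (0.573). The 1 higher was CXCR5, a gene of the sort, which limma called without replicate 2 (adjusted p = 0.0395). The naive list holds the sort gene CCR7, so the sort itself adds to both lists between populations. BCL6, the regulator of that programme, was at 29.3 ± 3.38 FPKM in CXCR5high (n = 3, 66.9 in replicate 2) and 31.1 ± 5.35 in CCR7high, PDCD1, which encodes PD-1, at 77.0 ± 26.4 (31.5) against 57.0 ± 20.7, and TIGIT at 105 ± 13.6 (376) against 109 ± 37.6. Cell cycle genes had a median of 0.78 (0 of 26 called, camera adjusted p = 8.81e-09, adjusted p = 0.504 with an estimated correlation), with MKI67 at 16.7 ± 8.47 (n = 3, 93.8 in replicate 2) against 14.6 ± 5.54. B cell markers had a median of 1.83 (0 of 19 called, camera adjusted p = 1.96e-10, adjusted p = 0.504 with an estimated correlation) and 0.54 without replicate 2 (0.00142), higher in 3 of 3 donors. Type I interferon genes had -1.22 (0.000569, 0.673 with an estimated correlation), -0.77 without CCR7high replicate 3 (0.383) and -0.24 with the donor block (0.14). Glycolysis had 0.68 (3.8e-05, 0.582) and 0.23 without replicate 2 (0.341), and ribosomal proteins 0.61 (8.74e-25, 0.504). The ribosomal list was lower in 1 of 3 donors (differences of -0.154 to 1.444). Its mean was 11.369 in CXCR5high replicate 5 and 10.392 in replicate 2, but 9.845 and 9.874 in replicates 1 and 4. Quantile normalization moved the median of all genes in this comparison from -0.23 to 0.01 and median-ratio scaling moved it to -0.31. Chemokines and their receptors had a median of -0.56 (0.499) with all libraries and 0.52 without replicate 2 (0.0233, 0.686 with an estimated correlation). The other lists had no camera adjusted p under 0.05, and their medians include replicate 2. They were -0.72 for inhibitory receptors, -0.10 for effector transcription factors, -0.29 for tissue residency, -0.32 for regulatory T cell genes, -0.00 for stress genes and -0.44 for cytokines. For cell types they were -0.49 for CD8 identity, 0.45 for germinal centre B cells, 0.19 for plasma cells, -0.08 for CD4, 0.41 for myeloid, -0.12 for NK and 0.54 for stromal markers. Proteasome and antigen presentation genes had 0.28. Against the sign of its median, the NK list mean was higher in 3 of 3 donors (0.308 to 0.485). CD8 identity was likewise higher in 2 of 3 (-0.057 to 0.227), and germinal centre B cell and stromal markers were lower in 2 of 3. In the other lists most donors went with the median, except for stress genes, whose median was near 0.

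The comparison of lymph node CXCR5high with CD45ROlow asked how the follicular population differs from cells of naive phenotype. NKG7, a protein of cytotoxic granules, was at 1834 ± 1099 FPKM in CXCR5high (n = 3, 560 in replicate 2) and 33.6 ± 23.4 in CD45ROlow (n = 3), and rose by 5.58 (SE 0.754, adjusted p = 0.000814). GZMB rose by 5.53 (SE 0.91, 0.0028) and PDCD1 by 4.37 (SE 0.615, 0.00104), from 2.25 ± 1.54 FPKM. LEF1 fell by 5.36 (4.07e-05), from 520 ± 48.2 FPKM, and BACH2, a repressor of effector genes, was at 1.36 ± 0.579 (n = 3, 17.0 in replicate 2) against 57.3 ± 3.83. TRABD2A fell by 6.01 (SE 0.449, adjusted p = 3.28e-05), TXK by 5.29 (9.83e-05), CD248 by 5.55 (0.00026), ACTN1, which encodes an actin crosslinker, by 5.71 (0.000322), and MAL by 4.88 (0.000517). All of the named genes with a fitted change went the same way in 3 of 3 donors. The naming rule required this of genes picked by fold change, so it is no separate support for them.

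In all, 901 genes were called between CXCR5high and CD45ROlow (340 higher, 561 lower). The count was 2042 (1004 higher, 1038 lower) without CXCR5high replicate 2 and 2828 (1324 higher, 1504 lower) with the donor block, with 1978 genes shared. Both of these fits compare the same 3 donors and give the same fold changes, so they are not independent. It fell to 325, 452 and 427 without CD45ROlow replicates 1, 4 and 5. The higher genes made up 37.7% of calls as deposited and 54.5% after quantile normalization, which moved the median of all genes from -0.28 to -0.03. Further genes with the largest increases were DUSP4 (5.47), CST7 (5.11), HLA-DQA1 (5.10), HLA-DRB1 (5.02), PTMS (5.01), HLA-DRA (4.81), GZMA (4.78), LGALS3 (4.76) and the overlapping transcripts LINC00152 (5.29) and MIR4435-1HG (5.24), with adjusted p from 0.000833 to 0.0206. Without CXCR5high replicate 2 the change was 4.30 for HLA-DRB1, 3.95 for HLA-DRA (927 FPKM in that replicate), 3.48 for LGALS3 (828 FPKM), 6.05 for GZMA and -4.10 for CCR7. Lower were also CHRM3-AS2 (-5.21), ADAMTS10 (-4.98), VIPR1 (-4.72) and S100B (-4.59). FAM153A was at 50.7 ± 24.1 FPKM and SNORA71B at 36.5 ± 21.3 in CD45ROlow and both were listed at 0 in all 4 CXCR5high libraries. Of the sort genes, CXCR5 rose by 4.10 (adjusted p = 0.00354) and CCR7 fell by 3.26 (0.0149). CD8A differed by 0.30 (0.758), but by 0.99 without replicate 2 (0.0204), and was called with the donor block (0.0316). CD27 (0.25), CD8B (-0.63) and PTPRC (-0.13) were not called.

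Of the naive and recirculation genes 0 were called higher in CXCR5high than in CD45ROlow, 14 lower and the rest not (adjusted over the list alone 16 lower), with a median of -2.98 (camera adjusted p = 2.86e-18, 0.0192 with an estimated correlation). Of 26 cell cycle genes 14 were called higher and 0 lower (adjusted over the list alone 21 higher, median 2.39, camera adjusted p = 4.94e-21, 0.0236 with an estimated correlation). NUSAP1, a spindle protein, rose by 3.53 (adjusted p = 0.00196), STMN1 by 2.93 (0.00302), and MKI67, a marker of cycling cells, by 3.76 (0.00347, 3.13 without replicate 2), from 0.994 ± 0.787 FPKM. Of 22 follicular helper genes 9 were called higher and 1 lower (adjusted over the list alone 11 and 1, median 1.58, camera adjusted p = 2.62e-08, 0.0236 with an estimated correlation, and 0.112 without replicate 2). TOX2 rose by 3.90 (0.000733), TIGIT by 4.08 (0.0022), and IL6R fell by 3.37 (0.00165). The 9 include the sort gene CXCR5, and the 14 naive genes called lower include the sort gene CCR7. Cytotoxic molecules had 6 of 20 called higher and 0 lower (adjusted over the list alone 12 higher, 16 called without replicate 2 and 17 with the donor block), a median of 2.09 and camera adjusted p = 1.6e-10, and adjusted p = 0.177 with an estimated correlation. TNF rose by 4.49 (0.000733) and GZMK by 3.72 (0.00147). Proteasome and antigen presentation genes had 5 of 15 higher and 0 lower (adjusted over the list alone 9 higher, median 0.99, camera adjusted p = 4.97e-07, 0.0236 with an estimated correlation). CD74, the class II invariant chain, rose by 2.90 (0.00026) and HLA-DMA by 3.38 (0.000584).

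Effector transcription factors had 6 of 16 called higher and 0 lower between CXCR5high and CD45ROlow (median 1.07, camera adjusted p = 2.24e-05, adjusted p = 0.116 with an estimated correlation). TBX21, which encodes T-bet, rose by 3.82 (0.00132), PRDM1 by 3.38 (0.00354) and ZEB2 by 3.33 (0.0162). Inhibitory receptors had 4 higher and 2 lower of 16 (median 0.86, camera adjusted p = 0.0092, 0.268 with an estimated correlation). SLAMF7 rose by 3.84 (0.00185) and LAIR1 fell by 4.49 (0.000777). Chemokines and receptors had 3 of 17 higher and 0 lower (adjusted over the list alone 7 higher, 12 called without replicate 2, median 2.05, camera adjusted p = 3.01e-07, 0.224 with an estimated correlation). CCL5 rose by 4.68 (0.00111) and CXCR3 by 1.97 (0.0237). Tissue residency genes had 3 of 13 higher (median 0.60, camera adjusted p = 0.0013, 0.224 with an estimated correlation). RGS1 rose by 2.19 (0.00401) and ITGAE, which encodes CD103, by 2.08 (0.0215). B cell markers had 2 of 19 called higher, CD74 and HLA-DRA, which activated T cells also express (median 1.70, camera adjusted p = 5.67e-06, 0.354 with an estimated correlation), and a median of 0.36 without replicate 2 (0.0988). Camera also gave adjusted p under 0.05, lost with an estimated correlation, for regulatory T cell genes (median 1.22, camera adjusted p = 0.00158, adjusted p = 0.177 with an estimated correlation), cytokines and receptors (0.31, 0.0465, 0.224), plasma cells (0.34, 0.0109, 0.177), NK markers (0.93, 0.00771, 0.268) and glycolysis (0.85, 0.000454, 0.399). The cytokine list no longer passed without CD45ROlow replicate 1 (0.055) or 4 (0.0941) or CXCR5high replicate 1 (0.0816) or 5 (0.065), the plasma cell list without CD45ROlow replicate 1 (0.055) and glycolysis without CXCR5high replicate 2 (0.147). Camera gave no adjusted p under 0.05 for interferon (-0.72), stress (0.05), CD8 identity (-0.31), germinal centre B cell (1.17), CD4 (0.78), myeloid (-0.01), stromal (-0.67) and ribosomal (0.04) genes. These medians include replicate 2. Against them, the CD8 identity mean was higher in 3 of 3 donors (0.242 to 0.389). Germinal centre B cell markers were lower in 3 of 3 (-0.029 to -0.012) and ribosomal genes in 2 of 3. The other lists went with their medians in most donors.

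The comparison of lymph node CCR7high with CD45ROlow asked what distinguishes CCR7high memory cells from cells of naive phenotype. NKG7 was at 791 ± 212 FPKM in CCR7high (n = 4) against 33.6 ± 23.4 in CD45ROlow (n = 3) and rose by 4.86 (SE 0.754, adjusted p = 0.00728). CCL5, a chemokine of effector cells, rose by 4.52 (SE 0.665, 0.00649), from 54.3 ± 30.5 to 1110 ± 269 FPKM, and PDCD1 by 4.23 (SE 0.615, 0.00649), to 57.0 ± 20.7. NT5E, which encodes the ectoenzyme CD73, fell by 3.30 (0.00775), from 14.6 ± 2.26 to 0.657 ± 0.595, and BACH2 fell by 3.12 (0.0338), to 5.91 ± 1.85. IGF1R fell by 3.35 (0.00967), from 17.1 ± 5.49 to 0.820 ± 0.609. In all, 213 genes were called (93 higher, 120 lower), 970 (553 higher, 417 lower) without CXCR5high replicate 2, whose values enter the common variance, and 1079 (630 higher, 449 lower) with the donor block, with 793 shared by the last 2 fits, all in the same direction. The last 2 fits compare nearly the same libraries, so their agreement is not independent. Every library of both groups moved the count: it was 20, 100 and 86 without CD45ROlow replicates 1, 4 and 5, and between 92 and 116 without any one of CCR7high replicates 1, 3, 4 and 5. The higher genes made up 43.7% of calls as deposited, 60.8% after quantile normalization and 35.5% after median-ratio scaling.

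Others that rose from CD45ROlow to CCR7high were GZMB (5.12), CST7 (4.54), HLA-DQA1 (4.32), DUSP4 (4.199), PTMS (4.14), ZEB2 (3.90), PLEK (3.82) and the overlapping MIR4435-1HG (4.35) and LINC00152 (4.24), with adjusted p from 0.00728 to 0.0264. Lower were TRABD2A (-3.35, adjusted p = 0.00448), AK5 (-3.34, 0.00266), ACTN1 (-3.63), SPEG (-3.30), LEF1-AS1 (-3.19), SH3RF3 (-3.06), FAM153C (-3.03) and ZNF516 (-2.96), each named gene in 3 of 3 donors, and SNORA71B was listed at 0 in all 4 CCR7high libraries. Agreement of the 3 donors was required by the naming rule, so it is no separate support for these genes. CCR7 differed by -1.89 (adjusted p = 0.305), and was called without CXCR5high replicate 2 (0.00861) and with the donor block (0.00784). CXCR5 (0.10), CD8A (0.79), CD27 (-0.09), CD8B (-0.04) and PTPRC (0.28) were not called.

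Naive genes were lower and effector and follicular helper genes higher as lists in CCR7high than in CD45ROlow, and these held with an estimated correlation. Of 19 naive genes 7 were called lower and 0 higher (adjusted over the list alone 14 lower, 12 called without CXCR5high replicate 2 and 15 with the donor block, median -1.58, camera adjusted p = 2.13e-19, 0.0117 with an estimated correlation). LEF1 fell by 2.62 (0.00901) and CD55 by 1.80 (0.016). Of 22 follicular helper genes 5 were called higher and 0 lower (adjusted over the list alone 9 and 1, median 1.40, camera adjusted p = 3.52e-10, 0.0117 with an estimated correlation). TOX2 rose by 3.02 (0.0109), TIGIT by 3.63 (0.0135) and TOX, a factor of chronically stimulated T cells, by 2.51 (0.0171). Of 20 cytotoxic molecules 5 were called higher and 0 lower (adjusted over the list alone 10 higher, 15 called without CXCR5high replicate 2, median 2.63, camera adjusted p = 4.76e-18, 0.0486 with an estimated correlation, 0.121 with the donor block), and GZMK rose by 2.92 (0.0171). Of 16 effector transcription factors 4 were called higher (adjusted over the list alone 8, median 1.60, camera adjusted p = 9e-11, 0.0162 with an estimated correlation). TBX21 rose by 3.41 (0.00819), PRDM1 by 3.19 (0.0141) and BHLHE40 by 2.169. Of 16 inhibitory receptors 4 were higher and 1 lower (adjusted over the list alone 6 and 1, median 1.88, camera adjusted p = 7.28e-07, 0.0486 with an estimated correlation). SLAMF7 rose by 3.69 (0.00775) and LAG3 by 3.56 (0.0231). Of 26 cell cycle genes 3 were higher and 0 lower (adjusted over the list alone 12, 22 called with the donor block, median 1.58, camera adjusted p = 1.62e-18, 0.0243 with an estimated correlation). NUSAP1 rose by 2.79 (0.0215), MKI67 by 2.99 (0.0329) and RRM2 by 3.07 (0.0456).

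**Figure D4:**
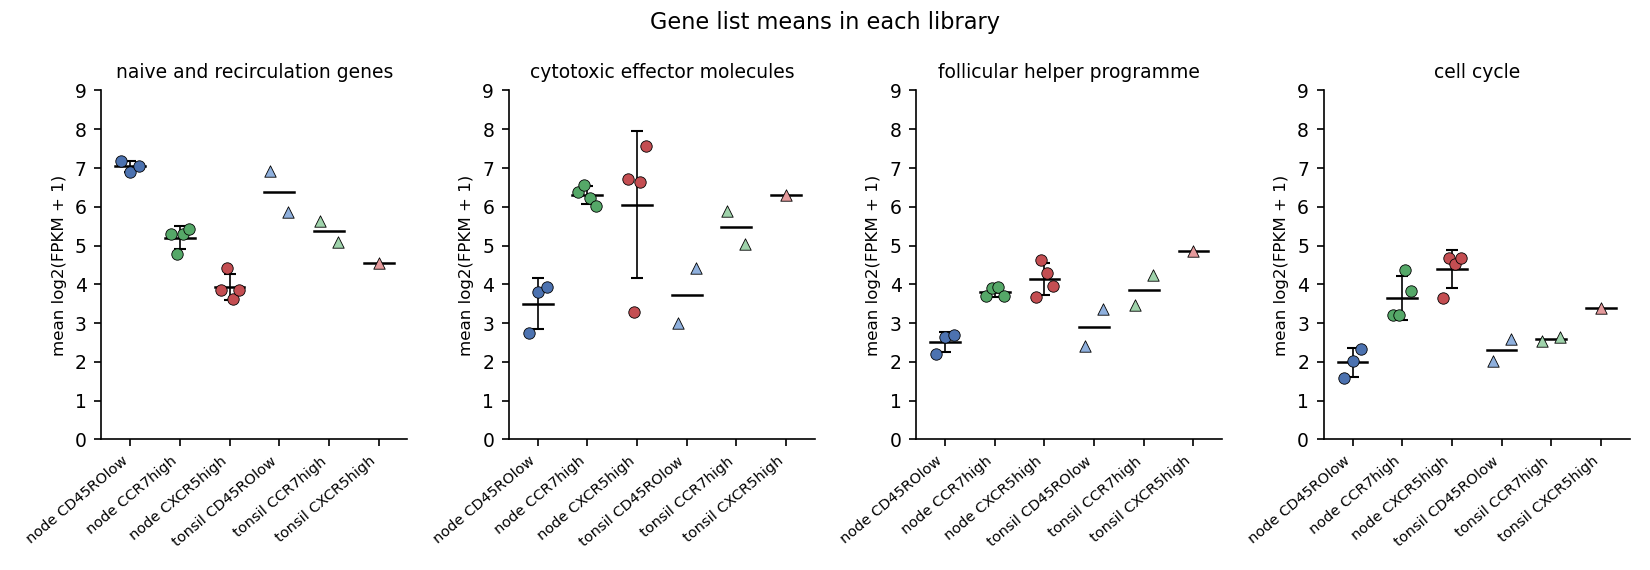
Each point is 1 library; the y axis is the mean log2(FPKM + 1) of naive, cytotoxic, follicular helper and cell cycle genes and the x axis the population (lymph node n = 3, 4 and 4, tonsil n = 2, 2 and 1). Bars are means, with SD where n is over 2; the naive list had a median difference of -1.58 and the cytotoxic list 2.63 between lymph node CCR7high and CD45ROlow.

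Smaller numbers of calls lay in the remaining lists of CCR7high against CD45ROlow. Chemokines and receptors had 1 of 17 called higher (adjusted over the list alone 14, 12 called without CXCR5high replicate 2, median 2.62, camera adjusted p = 1.52e-14, 0.0486 with an estimated correlation). Tissue residency had 1 higher, RGS1 by 1.69 (0.0458, list median 1.06, camera adjusted p = 1.58e-06, 0.0486 with an estimated correlation). Regulatory T cell genes had 2 higher (median 1.40, camera adjusted p = 5.93e-08, 0.0231 with an estimated correlation), TIGIT and CCR8, which was listed at 0 in all CD45ROlow libraries. Cytokines and receptors had TNF higher by 3.12 (0.0171, list median 0.85, camera adjusted p = 8.7e-05, 0.0249 with an estimated correlation), and proteasome and antigen presentation genes had CD74 higher by 2.19 (0.00649) and HLA-DMA by 2.65 (0.00807, list median 0.55, camera adjusted p = 1.05e-08, 0.0117 with an estimated correlation). Interferon genes (median 0.42, camera adjusted p = 0.00386, adjusted p = 0.548 with an estimated correlation), plasma cell (0.26, 0.0126, 0.0955), CD4 (0.94, 0.0492, 0.119), NK (1.23, 0.000467, 0.122), stromal (-1.43, 0.0048, 0.0955) and ribosomal genes (-0.60, 8.45e-14, 0.299) did not hold with an estimated correlation. The interferon list was higher in 1 of 3 donors, and its median was -0.064 without CCR7high replicate 3 (0.651) and 0.023 without CD45ROlow replicate 5 (0.247). The CD4 list no longer passed without CD45ROlow replicate 4 or 5 or CCR7high replicate 1, 3 or 4 (0.0631 to 0.102), nor the plasma cell list without CD45ROlow replicate 1 (0.103). Stress (0.00), CD8 identity (0.08), B cell (-0.14), germinal centre B cell (0.07), myeloid (-0.29) and glycolysis genes (0.33) had camera adjusted p over 0.05.

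Comparison of each sort between tissues asked which genes go with lymph node and HIV against tonsil without HIV. In CD45ROlow cells, KLF2, a factor that maintains quiescence and recirculation, was at 891 ± 163 FPKM in lymph node (n = 3) and 160 ± 110 in tonsil (n = 2), higher by 2.64 (SE 0.464, adjusted p = 0.046). SIK1, a kinase induced by cAMP, was at 296 ± 44.3 against 34.9 ± 12.9 (3.09, SE 0.433, 0.00756), ZNF331 at 257 ± 100.7 against 34.9 ± 16.2 (2.83, 0.0213), TMC8 at 335 ± 21.97 against 80.8 ± 17.5 (2.05, 0.0143), and CHRM3-AS2 at 53.9 ± 3.91 against 5.46 ± 3.36 (3.19, 0.023). CCDC64 was lower (-2.14, SE 0.298, 0.00756), at 44.5 ± 10.2 against 196 ± 12.2, and MIAT, a long noncoding RNA, was at 7.20 ± 3.04 against 55.1 and 274 in the tonsil libraries (-4.00, 0.046). Each named gene lay on its side in 3 of 3 lymph node libraries. In all, 19 genes were called (15 higher, 4 lower), but 125 (57 higher, 68 lower) without lymph node CXCR5high replicate 2, 36 and 1 without tonsil CD45ROlow replicates 1 and 2, 12 and 6 without lymph node CD45ROlow replicates 4 and 5. The naive list mean was 5.86 in tonsil CD45ROlow replicate 2, against 6.906 to 7.177 in the other CD45ROlow libraries and 5.64 and 5.099 in tonsil CCR7high. Its cytotoxic list mean was 4.426, against 2.747 to 3.944 and against 5.896 and 5.052. On both lists it lay between these populations. It is not among the doubtful libraries, and the CD45ROlow tissue differences and the interaction include it. CXCR5, CCR7, CD27, CD8A, CD8B and PTPRC were not called in any sort between tissues.

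In CCR7high cells, FCRL6, an inhibitory receptor of cytotoxic cells, was higher in lymph node (4.11, SE 0.687, adjusted p = 0.0311), at 58.1 ± 19.6 FPKM (n = 4) against 2.81 ± 2.74 in tonsil (n = 2). P2RX5, an ATP-gated channel, was lower (-1.96, SE 0.323, 0.0286), at 28.95 ± 6.89 against 114 ± 21.6, both in 4 of 4 lymph node libraries. IL17F, a cytokine of type 17 cells chosen after its values were seen, was lower by 4.30 on the log2 scale (-4.30, SE 0.64, 0.0161). In all, 17 genes were called (6 higher, 11 lower), 392 (113 higher, 279 lower) without lymph node CXCR5high replicate 2, 42 without that library and tonsil CCR7high replicate 2, 32 and 9 without tonsil CCR7high replicates 1 and 2, and 8 without each of lymph node CCR7high replicates 1, 4 and 5. Higher genes were 35.3% of calls as deposited and 53.6% after quantile normalization, which moved the median of all genes from -0.16 to -0.01. In CXCR5high cells the tonsil group was 1 library, so a difference of tissue cannot be separated from one of that library or donor. GNG4, a G protein subunit, was at 1.04 ± 1.03 FPKM (n = 3, listed at 0 in replicate 2) against 48.2 (-4.94, SE 0.679, 0.0152). CEP112 (-3.05), NTRK3 (-2.96), KCNIP2 (-2.34) and PPP1R2P9 (-2.52) were also lower. GNG4 and these 4 genes had levels under the naming rule and were chosen after their values were seen. The count there was 11 (1 higher, 10 lower), 33 without lymph node CXCR5high replicate 2, and 5, 6 and 5 without replicates 1, 4 and 5. Quantile normalization moved the median of all genes in this comparison from -0.34 to -0.00.

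Immediate early and stress genes, which respond within minutes to stimulation or handling, were the list with the smallest camera p between tissues in CD45ROlow and CCR7high cells. DNAJB1, a heat shock co-chaperone, was at 622 ± 115 FPKM against 198 ± 52.9 in CD45ROlow, 572 ± 89.4 against 196 ± 89.5 in CCR7high and 576 ± 57.8 (n = 3) against 262 in CXCR5high. DUSP1 was at 718 ± 111 against 159 ± 150 in CD45ROlow and 735 ± 202 against 184 ± 173 in CCR7high, and NR4A1, induced by receptor signals, at 171 ± 50.9 against 26.8 ± 22.1 and 80.5 ± 45.1 against 16.8 ± 5.03. None of 21 list members was called (limma), and adjusted over the list alone 8 were higher in CD45ROlow and 5 in CCR7high. The medians were 1.41 in CD45ROlow (camera adjusted p = 6.13e-15, adjusted p = 0.0645 with an estimated correlation), 1.63 in CCR7high (6.47e-17, 0.0428, and 0.47 without the doubtful libraries) and 1.03 in CXCR5high (3.96e-08, 0.295).

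Among CD45ROlow and CCR7high libraries the mean log2(FPKM + 1) of the glycolysis genes was highest in tonsil replicate 2 (8.408 and 8.45). ENO1, a glycolytic enzyme, was at 157 ± 13.7 FPKM in lymph node CD45ROlow against 502 and 1853 in tonsil replicates 1 and 2, and at 200 ± 40.7 against 610 and 1912 in CCR7high. The list medians, lymph node against tonsil, were -1.55 in CD45ROlow (0 of 17 called, adjusted over the list alone 1 higher and 3 lower, camera adjusted p = 1.37e-08, adjusted p = 0.423 with an estimated correlation) and -1.69 in CCR7high (0 called, adjusted over the list alone 1 higher and 12 lower, 3.96e-07, 0.496). Without tonsil CD45ROlow replicate 2 the CD45ROlow median was -0.67 (0.0652). In CD45ROlow, naive genes (median 0.64, 1 called, KLF2, 5.99e-06, adjusted p = 0.241 with an estimated correlation), stromal markers (0.92, 0.00921, 0.241) and ribosomal proteins (-0.27, 0.0116, 0.967) also had camera adjusted p under 0.05. The naive median was 0.26 without tonsil CD45ROlow replicate 2 (0.159), and the ribosomal median -0.0998 without tonsil replicate 1 (0.671), -0.17 without lymph node CD45ROlow replicate 4 (0.254) and -0.27 without lymph node CXCR5high replicate 2 (0.305). In CCR7high these were cell cycle genes (1.09, 2.96e-10, adjusted p = 0.237 with an estimated correlation), cytotoxic molecules (1.03, 0.000156, 0.536), effector transcription factors (0.62, 1.61e-05, 0.237), inhibitory receptors (0.36, 0.0204, 0.526), interferon genes (0.89, 1.15e-05, 0.536), ribosomal proteins (-0.74, 5.76e-16, 0.526), proteasome genes (0.10, 0.0495, 0.496) and B cell markers (-2.12, 5.96e-05, 0.536), the last with a median of -0.74 without the doubtful libraries (0.67). The interferon list had its highest mean in lymph node CCR7high replicate 3 (7.602), and without it the median was 0.27 (0.0684). Inhibitory receptors no longer passed without that library (0.107) or tonsil CCR7high replicate 2 (0.155), nor did proteasome genes without that library (-0.014, 0.194), either tonsil CCR7high library (0.0719 and 0.121) or lymph node CXCR5high replicate 2 (0.0513). In CXCR5high they were cell cycle (1.16, 4.27e-10, adjusted p = 0.295 with an estimated correlation), ribosomal (0.58, 1.16e-17, 0.649), effector transcription factor (0.37, 0.0497, 0.649), CD4 (-0.995, 0.0497, 0.295) and proteasome genes (0.13, 0.0497, 0.55). Quantile normalization brought the last to -0.20 and the ribosomal median to 0.019. Effector transcription factors no longer passed without lymph node CXCR5high replicate 1 (0.197) or 4 (0.0698), CD4 genes without replicate 1 (0.197), 4 (0.123) or 5 (0.0726), and proteasome genes without replicate 2 (0.0867) or 5 (0.146).

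Within tonsil, CCR7high against CD45ROlow (n = 2 each) asked for the same memory difference without HIV. HLA-DQA1 differed by 4.35, RAB31 by 2.05, NXPH4 by 1.93, TAS2R6 by -1.36 and the small nucleolar RNA SNORA21 by 5.43, none called (adjusted p = 0.549 each). CXCR5 differed by 2.47 and CCR7 by -0.63 (adjusted p = 1 each). The noncoding RP11-395C3.1 was called, at a mean log2(FPKM + 1) of 2.25 in CCR7high and 0 in CD45ROlow (adjusted p = 0.00619, chosen after its values were seen). It was the single call of limma (371 genes had an unadjusted p under 0.05). The count was 0 without tonsil CD45ROlow replicate 1 or lymph node CXCR5high replicate 2, 5 without CD45ROlow replicate 2, and 6 and 2 without CCR7high replicates 1 and 2. B cell markers had a median of 2.47 (0 of 19 called, camera adjusted p = 3.94e-14, adjusted p = 0.137 with an estimated correlation) and 0.92 without the doubtful libraries (0.00169). Naive genes had -0.89 (1.26e-12, adjusted p = 0.0696 with an estimated correlation, 0.0321 with the donor block), cytotoxic molecules 1.85 (4.57e-10, 0.143), chemokines 1.74 (6.66e-11, 0.117) and follicular helper genes 0.77 (1.67e-06, 0.0781). Lists of regulatory T cell (0.98), tissue residency (0.55) and proteasome genes (0.23, adjusted over the list alone 3 higher) each had camera adjusted p = 8.35e-05, and adjusted p = 0.117, 0.117 and 0.0917 with an estimated correlation. NK (0.83, 0.00317), effector transcription factor (0.60, 0.00414), cytokine (0.46, 0.00467), plasma cell (0.65, 0.00977), inhibitory receptor (0.57, 0.0108), myeloid (0.77, 0.0435) and ribosomal genes (-0.10, 0.0444) were lost as well, at adjusted p = 0.117 to 0.816 with an estimated correlation. Effector transcription factor, inhibitory receptor, tissue residency, myeloid and ribosomal genes each went in opposite directions in the 2 donors. Without tonsil CD45ROlow replicate 1 the lists that no longer passed were regulatory T cell (0.199, 0.669), tissue residency (0.154, 0.339), effector transcription factor (-0.076, 0.669), inhibitory receptor (-0.073, 0.726), cytokine (0.234, 0.23), plasma cell (0.166, 0.669), NK (0.54, 0.0547), follicular helper (0.46, 0.0859) and ribosomal genes (0.036, 0.669). Without tonsil CCR7high replicate 1 they were tissue residency (0.22, 0.151), inhibitory receptor (0.28, 0.151), cytokine (0.11, 0.165) and NK genes (0.485, 0.0583), and the ribosomal list passed in the opposite direction (0.20, 0.0191). Without CD45ROlow replicate 2 they were proteasome (-0.19, 0.309) and myeloid genes (0.63, 0.248), without CCR7high replicate 2 plasma cell (0.37, 0.428) and myeloid genes (0.065, 0.251), and without lymph node CXCR5high replicate 2 myeloid (0.058) and ribosomal genes (0.098).

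The interaction asked whether the CCR7high against CD45ROlow difference was larger in lymph node than in tonsil. Among genes that the rule allows to be named, ABCA1, a lipid exporter, had the smallest adjusted p (-2.63, adjusted p = 0.311). After it came the ribosomal pseudogene RPL12P18 (-2.56, 0.466), LINC01023 (-2.85, 0.466), XKRX (-1.53, 0.877) and ARRDC4, a relative of a glucose-sensing arrestin (-2.24, 0.877). Over all genes the smallest limma adjusted p was 0.0628. No gene was called by limma (387 had an unadjusted p under 0.05). The count was 53 without a filter on low values, 2 with donor as a random block, 1 without tonsil CD45ROlow replicate 2, 2 without tonsil CCR7high replicate 1 and 1 without lymph node CCR7high replicate 5.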

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

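Of the tests below, those of B cell RNA in both libraries, of low reads as the source of the B cell markers and of tissue handling were chosen only after the result was seen; the others were written before.

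Of 183 checks for a library far from the other 3 of its lymph node group, 28 exceeded the critical value of Dixon's ratio (gap to the nearest library divided by the range); chance flags about 1 in 20 groups. Of these, 12 lay in lymph node CXCR5high replicate 2: genes with an FPKM of at least 1 (ratio 0.848), the means of chemokines (0.842, 1.403 against 4.951 to 5.619), tissue residency (0.882), CD8 identity (0.877), B cell (0.841), germinal centre B cell (0.929, 4.157 against 1.212 to 1.42), NK (0.889, 0.634 against 2.72 to 2.98) and glycolysis genes (0.89, 8.655 against 6.377 to 6.628), and CCR7 (0.855), CD8A (0.892), HLA-DQA1 (0.952) and LGALS3 (0.866). In that library 19 of 19 B cell markers lay more than 1 log2 unit above the other 3, and their mean lay 4.41 above the highest of these, whose SD was 0.434. This argues against few reads or little RNA as the source of these markers. The values are consistent with RNA of B cells beside that of CD8 T cells, a hypothesis, since the sort for CD8 T cells would remove B cells. For the genes at 0, a gene at 0 had the lower level elsewhere in 0.697 of pairs, between the bounds set for and against few reads, so low input stays open. No biological explanation was tested, since the design gives none for 1 library.

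Tonsil CCR7high replicate 2 stood out by CXCR5 (39.5 FPKM), though its group is too small for the ratio, and 18 of 19 B cell markers lay more than 1 log2 unit above replicate 1, which is consistent with RNA of B cells. By the ratio of CXCR5 to CD79A, B cells would bring at most 5.85 FPKM of CXCR5 with the ratio of lymph node CXCR5high replicate 2, but at most 103 with that of the tonsil CXCR5high library; both are upper limits because T cells of these libraries add CXCR5, and the second exceeds the level seen. The first limit lies below the level seen, but it holds only if B cells of both libraries have the same ratio. It also rests on 1 lymph node library that listed 68.6% of genes at 0. The test set beforehand therefore did not decide whether B cell RNA brought the CXCR5. Over 12 genes lower in lymph node CXCR5high, the library lay 0.417 of the way from tonsil CCR7high replicate 1 to tonsil CXCR5high, between the bounds set for and against a library of the CXCR5high sort under this label. CCR7 was at 136.67 FPKM, against 173.49 in replicate 1 and 70.71 in tonsil CXCR5high, and GNG4 at 8.88 against 1.44 and 48.19, both nearer to replicate 1, but with so few libraries the label stays open.

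The median of the stress genes was higher in lymph node than in tonsil in all 3 sorts, but 0 of 21 were called in each, and with an estimated correlation the adjusted p was 0.0645 in CD45ROlow, 0.0428 in CCR7high and 0.295 in CXCR5high. Scaling between libraries is argued against as the whole cause: under quantile normalization or median-ratio scaling the median change kept at least 0.648 of its deposited size in each sort (quantile medians 1.64, 1.86 and 0.67 in CD45ROlow, CCR7high and CXCR5high). Handling of the tissues cannot be told apart from tissue or HIV status, because 0 donors gave both tissues. Tissue and HIV status themselves stay open and untested as biological explanations. The 3 sorts share donors, and the 5 tonsil libraries came from 2 donors, so their agreement is not independent.

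The remaining 16 ratios were in other libraries. In lymph node CCR7high they were replicate 3 for its median correlation with other libraries (0.863, 0.859 against 0.904 to 0.911), glycolysis (0.857), ZEB2 (0.8292), SIK1 (0.876) and ARRDC4 (0.913), replicate 5 for NKG7 (0.881), GNG4 (0.904), NTRK3 (1) and RPL12P18 (1), and replicate 1 for SNORA21 (1). In lymph node CXCR5high they were replicate 1 for cell cycle genes (0.84, 3.656 against 4.526 to 4.692) and SNORA21 (1), and replicate 4 for IGF1R (0.861), NT5E (0.923), SH3RF3 (0.898) and LINC01023 (1). Ratios of 1 come from genes at 0 in the other 3 libraries.

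Camera on the interaction (whether the difference between CCR7high and CD45ROlow differed between lymph node and tonsil) gave an adjusted p under 0.05 for 14 lists. The medians were 0.61 for follicular helper (adjusted p = 0.00545), -0.73 for naive (5.62e-05), 1.26 for cytotoxic (5.62e-05), 0.94 for effector transcription factor (4.69e-06), 1.25 for inhibitory receptor (0.000943), 1.33 for cell cycle (1.02e-13), 0.60 for interferon (0.00103, 0.09 with the donor block), 1.18 for chemokine (0.0122), 0.70 for regulatory T cell (0.0202), -2.58 for B cell (6.62e-08), -0.53 for myeloid (0.0202), -1.65 for stromal (0.000998), 0.30 for proteasome (0.0134) and -0.47 for ribosomal genes (7.71e-08). None held with an estimated correlation (lowest adjusted p = 0.158). With single libraries left out, each list except cell cycle and stromal genes lost its adjusted p under 0.05 at least once. Without tonsil CD45ROlow replicate 2 the lists that no longer passed were follicular helper (0.17, adjusted p = 0.638), naive (-0.23, 0.336), cytotoxic (0.64, 0.113), effector transcription factor (0.31, 0.113), inhibitory receptor (0.098, 0.628), chemokine (-0.049, 0.871), regulatory T cell (-0.19, 0.871) and myeloid genes (-0.47, 0.113). Without tonsil CCR7high replicate 2 they were B cell (-1.41, 0.226), ribosomal (-0.18, 0.271), interferon (0.17, 0.101), chemokine (0.91, 0.216), myeloid (-0.46, 0.125) and proteasome genes (0.21, 0.0565). Without tonsil CD45ROlow replicate 1 they were interferon (-0.14, 0.999) and proteasome genes (-0.014, 0.608), and without tonsil CCR7high replicate 1 follicular helper (0.69, 0.379) and regulatory T cell genes (0.17, 0.187). Omission of lymph node libraries cost lists too. Without CCR7high replicate 3 they were interferon (0.094, 0.294), chemokine (0.99, 0.0701), regulatory T cell (0.19, 0.102), myeloid (-0.37, 0.0701) and proteasome genes (0.27, 0.0701). Without CD45ROlow replicate 1 they were chemokine (0.95, 0.0854) and regulatory T cell genes (0.51, 0.109), and without replicate 5 interferon (0.19, 0.108) and myeloid genes (-0.51, 0.0514). Without CXCR5high replicate 2 they were regulatory T cell (0.0988) and proteasome genes (0.0538). The chemokine median ran up to 1.72 and the B cell median down to -3.78. All 26 cell cycle genes were positive with all libraries.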

How the results depend on the processing

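Omission of lymph node CXCR5high replicate 2 from comparisons without its group, omission of lymph node CXCR5high replicate 2 with tonsil CCR7high replicate 2 and the B cell covariate were chosen after seeing the data. Of 7430 values of named genes under the alternatives, 6782 stayed on their side of the threshold (changes of sign in genes not called in either fit are not counted), 316 no longer passed, 332 newly passed and 0 reversed. These genes include those picked because an alternative called them between CXCR5high and CCR7high. The alternatives were omission of CXCR5high replicate 2, omission of both doubtful libraries, and the fixed donor block. Part of the newly passed values was thus built in by that choice. Lists were followed through 1772 values for the 88 list results that passed with all libraries. Of these values, 1491 stayed on their side, 266 no longer passed and 15 reversed. Lists that passed only under an alternative are not counted. With an estimated correlation 16 of the 88 held. Of 158 counts of calls, 65 stayed within 1.5 times. Counts follow in the order CXCR5high against CCR7high, CXCR5high against CD45ROlow, CCR7high against CD45ROlow (lymph node), lymph node against tonsil in CD45ROlow, CCR7high and CXCR5high, tonsil CCR7high against CD45ROlow, and interaction; with all libraries they were 0, 901, 213, 19, 17, 11, 1 and 0. A pseudocount of 0.1 gave 0, 636, 80, 6, 6, 2, 1 and 0, and 0.5 gave 0, 834, 178, 14, 16, 3, 1 and 0. No filter gave 0, 1099, 332, 118, 134, 426, 67 and 53, and an FPKM minimum of 5 gave 2, 620, 136, 14, 10, 4, 0 and 0. Quantile normalization gave 3, 1198, 439, 18, 28, 4, 0 and 0, and median-ratio scaling 5, 935, 245, 17, 17, 6, 1 and 0. Array weights gave 52, 3520, 3066, 168, 753, 316, 0 and 0, with a weight of 0.03 for CXCR5high replicate 2. The compared groups alone gave 0, 323, 1625, 5, 128, 0, 0 and 0, and no variance trend 1, 850, 194, 13, 14, 5, 0 and 0. The fixed donor block gave 20, 2828 and 1079 in lymph node, 1 in tonsil and 0 for the interaction, and cannot estimate tissue differences; the random block gave 14, 1684, 560, 16, 15, 14, 1 and 2. Without both of these libraries (lymph node CXCR5high replicate 2 and tonsil CCR7high replicate 2) the counts were 10, 1938, 937, 132, 42, 52, 1 and 0, and with the B cell covariate 0, 965, 505, 50, 65, 12, 0 and 0. Omission of single libraries gave 0 to 15, 325 to 2042, 20 to 970, 1 to 125, 8 to 392, 5 to 33, 0 to 6, and 0 to 2. Reversed lists, by median or by the direction of the test where the median kept its sign, follow, with the range over omission of single libraries in brackets. With the B cell covariate they were glycolysis between CXCR5high and CCR7high (7.43e-06), B cell markers between tissues in CCR7high (-0.079) and within tonsil (-0.068), and in the interaction chemokines (-0.60), B cell markers (-0.33) and ribosomal genes (-0.25). That covariate is the mean of the B cell markers, so it moves their own list toward 0 by construction. Reversals of the B cell list under it therefore say nothing about the data. Quantile normalization reversed proteasome (-0.20) and ribosomal genes (0.019) between tissues in CXCR5high. Without tonsil CCR7high replicate 2, B cell markers between tissues in CCR7high were at -0.74 (-3.73 to -0.74). Without tonsil CD45ROlow replicate 1, reversed lists within tonsil were effector transcription factors at -0.076 (-0.076 to 1.19), inhibitory receptors at -0.073 (-0.073 to 1.02) and ribosomal genes at 0.04 (-0.43 to 0.20, the last without CCR7high replicate 1), and in the interaction interferon genes at -0.14 (-0.14 to 1.52). Without tonsil CD45ROlow replicate 2, regulatory T cell genes in the interaction were at -0.19 (-0.19 to 1.18). For the other changes the cause was not tested. Read counts were not used here, so what depth limits is unknown.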

Other observations

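Among 35 splits of the 7 lymph node libraries of CCR7high and CD45ROlow, 1 (the real one) called as many as 213 genes, and the highest other called 2. For CXCR5high against CD45ROlow 1 of 35 called as many as 901, and the highest other called 364. Libraries of 1 donor are correlated, and only 8 of the splits part as many as 3 donor pairs, too few for a share under 0.05. The highest others among these 8 called 1 and 364. For CXCR5high against CCR7high with all libraries, 35 of 35 splits called at least the real 0 genes (highest other 1), which any split does, so this count tests nothing. Without CXCR5high replicate 2, 1 of 35 splits called as many as the real 15 genes (highest other 3). Of these too, only 8 part 3 donor pairs, too few for a share under 0.05, and the highest other among them called 0.

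Means of some genes lay in order across the lymph node populations. LAIR1, an inhibitory collagen receptor, was at 55.5 ± 7.86 FPKM in CD45ROlow, 8.67 ± 3.23 in CCR7high and 2.78 ± 2.27 in CXCR5high (n = 3, listed at 0 in replicate 2), and IL6R, a subunit of the IL-6 receptor, at 22.3 ± 12.3, 6.004 ± 2.89 and 1.41 ± 1.09. TNF ran the other way, at 1.00 ± 0.518, 17.95 ± 10.5 and 60.9 ± 39.1, and DUSP4, a phosphatase of MAP kinases, at 1.74 ± 1.59, 48.9 ± 24.6 and 103 ± 33.8 (144 in replicate 2). No trend over the populations was tested.

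Glycolysis means separated the tonsil donors more than the sorts: 6.855 and 7.151 in CD45ROlow and CCR7high of replicate 1, and 8.408 and 8.45 in replicate 2, against 6.108 to 6.301 and 6.07 to 6.523 in lymph node. No explanation was tested.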
